A study of Homo sapiens with 13 samples.

How the data were processed

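TE-7, an established human cell line of esophageal epithelium, was exposed to interleukin-13 (IL-13), a type 2 cytokine, at 100 ng/ml. RNA was sequenced with and without IL-13 at 2, 6 and 24 hr, which gave 6 RNA libraries, 1 for each treatment and time. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of H3K4me3, H3K9Ac and H3K27Ac, which are histone marks of active promoters and enhancers, was done with and without 6 hr of IL-13 and gave 6 libraries, 1 for each mark and treatment. The input DNA library was not used here. With 1 library in each group there is no replicate check of any single comparison, and no p-value was computed across genes within a pair of libraries.

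Expression values as RPKM, which scales reads to gene length and to all mapped reads, were deposited by the authors for 23637 gene symbols, per the file headers. The same tables hold a log2 ratio, a p-value and an adjusted p-value made by the authors, per the file headers. The submitters' processing notes name TopHat2 2.0.9 and DESeq for RNA, and Bowtie 1.0.0, MACS2 2.0.10.20130712 and DESeq for ChIP-seq, with build hg19 (GRCh37). The way reads were counted, the annotation release and the pooling of read sets are not given in the sources used here. For each mark the authors deposited a rescaled log2 ratio of the peak (M), a mean log2 level (A) and the −log10 of a p-value, per the file headers, whose column names are those of the MAnorm method. Peaks were listed by the transcription starts to which they had been assigned, and the positions given here are those starts. Neither headers nor labels state which library of a mark was treated. They are therefore called library 1 and library 2, M is log2 of library 1 over library 2, and no direction of treatment was assigned to any peak. For the same reason 6 columns of raw reads per library were not used.

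The design had been written for read counts. Because the tables hold RPKM, the fallback written with it was used, and no count model was fitted. The log2 ratio of IL-13 over control was computed on log2(RPKM + 0.1), which understates the change of genes with low values, and a fold is the plain ratio of RPKM. A gene was counted as higher or lower when it differed at least 2-fold on the log2(RPKM + 0.1) scale and reached an RPKM of at least 1 in the higher library. No fold is given against a value listed at 0. The same rule was applied between control libraries of different times. The effect shared by the 3 times was tested with limma 3.58.1 on log2(RPKM + 0.1), with time and treatment as terms, over genes with an RPKM of at least 1 in at least 3 libraries and a Benjamini-Hochberg adjusted p under 0.05. Its p-values measure the spread over the 3 times, and nothing in the labels says that libraries came from separate cultures. The median log2 ratio of each of 18 gene lists was placed among 10000 random lists of equal size matched on mean expression in 20 bins, and percentiles at or under 2.5 or at or above 97.5 were taken as outside the central 95%. A peak listed at several starts was counted once when its values were identical and the starts lay within 20 kb of each other. A peak was counted as higher in a library when M was at least 1 in size and its level, computed from M and A, was at least 30 in the higher library. The promoter peak of a gene is the one at the gene's start in the RNA tables, with the highest level where several were listed. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

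Depth was read from the low values and is given in megareads (M reads). In genes of 1 exon, RPKM times length lay on multiples of fixed steps, within a tolerance of 0.5%, in 91.2% to 95.9% of low values. At 24 hr a single step gave 13.6 M reads for the control and 14.0 M for the IL-13 library. The other 4 libraries lay on sums of 2 steps, as the mean of 2 read sets gives. These sets held 26.9 and 15.7 M reads in the control at 2 hr, 16.1 and 13.0 M with IL-13 at 2 hr, 15.7 and 15.3 M in the control at 6 hr, and 18.3 and 16.4 M with IL-13 at 6 hr. The controls at 2 and 6 hr had the step of 31.84 in common and 359 identical values above 0, against at most 1 identical value in each of the other 14 pairs of libraries, so a read set appears to have entered both. One read in a gene of 70 bp was worth 1.05 RPKM in the control at 24 hr and at most 0.549 RPKM at 2 and 6 hr. Exon lengths of spliced genes were not used, so no counting interval is given for them.

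The lists, the size rule, the tests of the comparisons and most alternatives were chosen before the data were examined, and the closing parts say which of their tests were not. The genes named are, for each time, the 10 with the largest and the 10 with the smallest log2 ratio that passed the size rule, up to 4 members of each list that passed it, and CCL26, SOCS1 and CAPN14. Some genes that this rule takes, and a gene list, are not reported here. For each mark they are the 5 peaks with the largest and the 5 with the smallest M, the peaks of these 3 genes, and up to 5 promoters of genes higher at 6 hr. The limit of 300 bp, the extension of the naming to 20 genes of at least 300 bp, the RPKM minimums of 0.5 and 3, the filter of the limma fit, the leaving out of brain genes, the promoter medians of genes of at least 300 bp, and median-ratio scaling for lists and control pairs were chosen after the data had been seen. The limma fit, the list percentiles, the size rule and the read steps were tested on simulated data, and the peak rule and the comparisons of marks were not. For the effect shared by the 3 times, limma recovered 98% of 100 genes changed 2-fold and 100% of 100 changed 4-fold. It made 9 false calls among 11953 genes. The simulated libraries were independent and shared no read set, and each changed gene moved alike at all 3 times. The recovered share is therefore no measure of what the fit could find in the real libraries. Of simulated lists at 6 hr, 4.5% of the unchanged ones fell outside the central 95%, and the size rule at 6 hr found 100 of 100 genes raised and 100 of 100 lowered 4-fold. The read steps were recovered in 18 of 20 simulations.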

Results

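The series asked how esophageal epithelial cells respond to IL-13. RNA was measured in control and IL-13-treated TE-7 cells at 2, 6 and 24 hr, and 3 active histone marks at 6 hr. Each of the 12 libraries compared is the only one of its group. Between 11794 and 12306 genes reached an RPKM of 1 in each RNA library.

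CCL26 (chromosome 7, 75398842 to 75419064, minus strand, hg19), the eosinophil chemokine eotaxin-3, was 4.29-fold higher at 2 hr, 8.75-fold at 6 hr and 30.1-fold at 24 hr, where it reached 166 RPKM. SOCS1 (chromosome 16, 11348274 to 11350039, minus strand), a feedback inhibitor of cytokine signalling, had its largest ratio early, at 4.74-fold, 4.37-fold and 2.25-fold over the 3 times, and with a pseudocount of 1 its log2 ratio at 24 hr was 0.90, under the 2-fold limit. CAPN14 (chromosome 2, 31395922 to 31440411, minus strand), an esophageal calpain, did not exceed 0.392 RPKM in any library and so was not compared. In the authors' deposited table CCL26 passed an adjusted p under 0.05 at 24 hr only, and SOCS1 at 6 hr only.

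**Figure D1:**
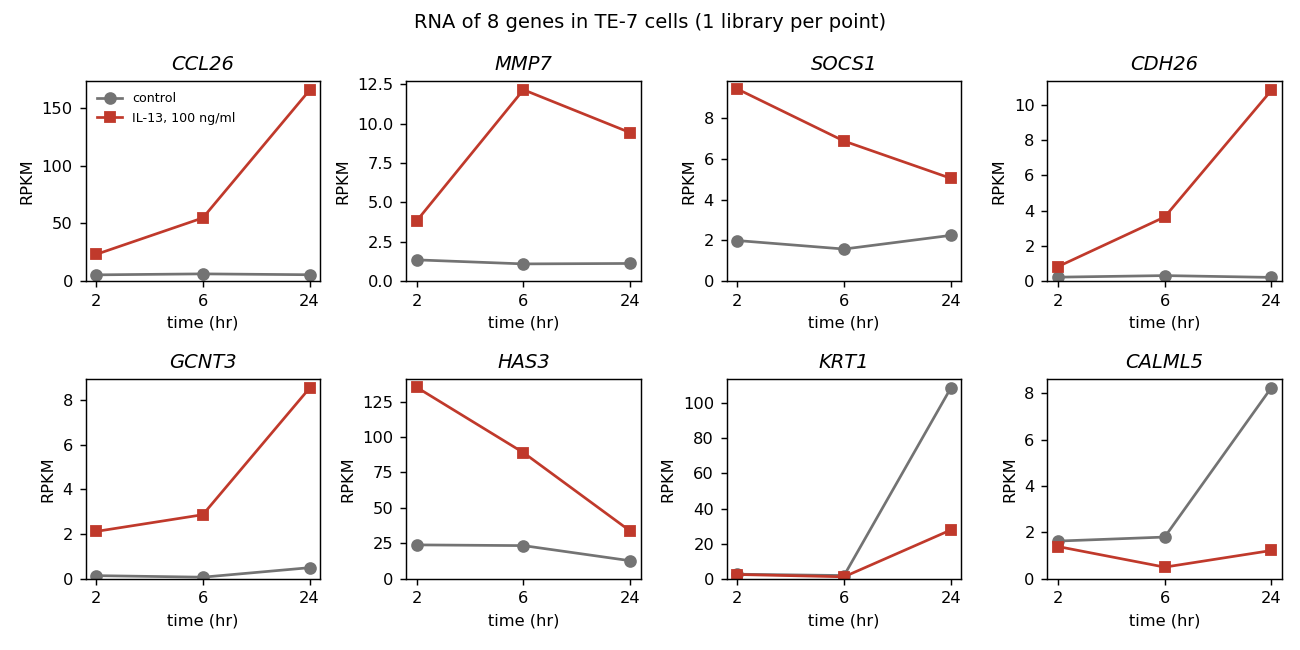
RPKM (linear axis) of 8 genes in control (grey circles) and IL-13-treated (red squares) TE-7 cells at 2, 6 and 24 hr, 1 library for each point, so no error bars can be drawn. CCL26 stands at 166 RPKM with IL-13 at 24 hr, MMP7 at 12.2 RPKM with IL-13 at 6 hr, and KRT1 stands at 109 RPKM in the control and 27.8 RPKM with IL-13 at 24 hr.

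The 2 hr comparison asked which transcripts differ earliest. GCNT3, a glycosyltransferase of mucin synthesis, stood at 0.141 RPKM in the control and 2.12 with IL-13. HAS3, a hyaluronan synthase, stood at 23.9 RPKM in the control and 135 RPKM with IL-13, and LURAP1L at 1.09 and 7.01. The serine protease inhibitors SERPINB4 and SERPINB3 were 6.33-fold and 5.16-fold higher, although these near-identical genes can share reads. CISH, another inhibitor of cytokine signalling, was 4.6-fold higher, HS3ST1, a heparan sulfate sulfotransferase, 4.69-fold, and FAM115C 7.67-fold. Transcription factors were among them too, with BCL11B at 3.94-fold, ARID5B at 3.36-fold, ID3 at 2.95-fold and MEOX1 at 3.6-fold. In all, 79 genes were higher and 41 lower among 12005 compared, and 47 and 22 among the 11837 of at least 300 bp. Without a minimum RPKM the balance turned, at 187 higher and 337 lower. Of the higher genes, only GCNT3 and HAS3 passed an adjusted p under 0.05 in the authors' deposited table. Of the 10 largest ratios, 8 belonged to microRNA or small nucleolar RNA genes shorter than 300 bp, each listed at 0 in the control, for example MIR4722 and SNORD59A.

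Of the 41 lower genes at 2 hr, 19 were shorter than 300 bp and 14 were on a list of brain genes. SNAP25, a protein of synaptic vesicle fusion, was at 3.57 RPKM in the control and listed at 0 with IL-13. GFAP, the astrocyte filament protein, MT3, a brain metallothionein, and PTGDS, a prostaglandin synthase, stood at 2.06, 1.44 and 1.12 RPKM in the control and were also listed at 0 with IL-13. UCHL1, a neuronal hydrolase, was at 2.09 and 0.0342 RPKM. All 14 were among the 22 lower genes of at least 300 bp. The other 8 include ANXA8, at 4.04 and 1.80 RPKM, SDCBP2, at 2.52 and 1.06 RPKM, and TMX2-CTNND1, a read-through transcript that overlaps its component genes. The 12 brain genes plotted, which were picked after their values had been seen, were each higher in the control at 2 hr than in all 5 other libraries, the other controls included.

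**Figure D2:**
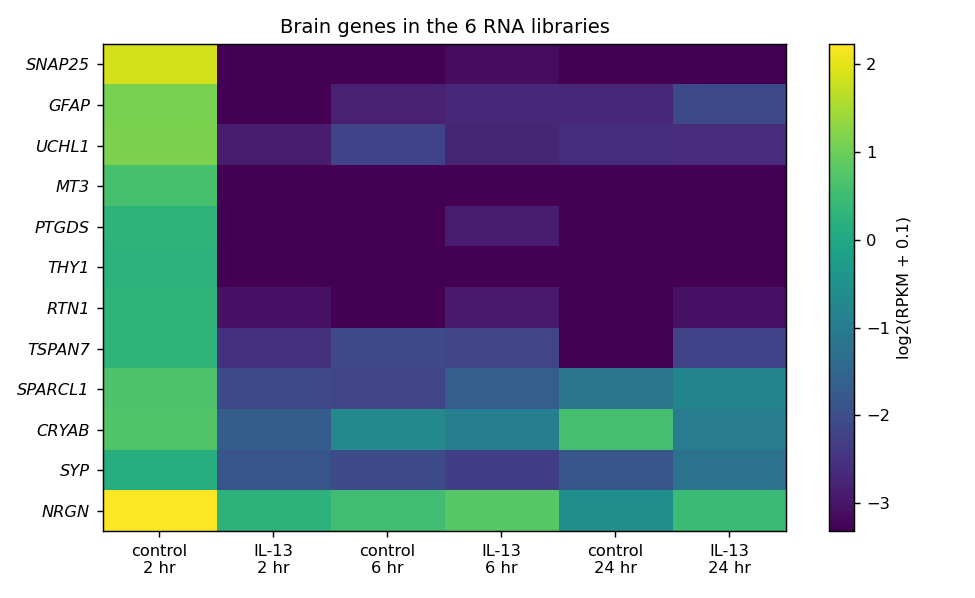
Colour gives log2(RPKM + 0.1) of 12 brain genes in the 6 RNA libraries, 1 column per library. All 12 are brightest in the control at 2 hr, where SNAP25 stands at 3.57 RPKM and NRGN at 4.6 RPKM.

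The 6 hr comparison is the one matched in time by the histone marks. GCNT3 stood at 0.0720 RPKM in the control and 2.87 with IL-13, SERPINB4 was 18.9-fold higher, SERPINB3 14.8-fold, LURAP1L 13-fold, MMP7, an epithelial matrix metalloproteinase, 11.1-fold, and CDH26, a cadherin of epithelium, 11.6-fold. HAS2 stood at 7.77 RPKM in the control and 43 with IL-13. HS3ST1 was 7.0-fold, SECTM1 4.75-fold, TNIK 5.42-fold, ADAMTS15 4.79-fold, LIFR, a receptor of interleukin-6 family cytokines, 4.52-fold and LOXL4 4.14-fold higher. ANO1, a calcium-activated chloride channel, stood at 31.7 RPKM in the control and 113 RPKM with IL-13. Fewer genes were lower, and 25 of the 38 were shorter than 300 bp. Among the longer ones were MALL at 40.03 and 16.7 RPKM, LCN2 at 4.53 and 1.95, CALML5 at 1.80 and 0.503, DUSP10 at 3.68 and 1.63, GRHL3 at 1.21 and 0.495, and LRRC24 at 1.03 and listed at 0. The short genes MIR1182, SNORD45B and SNORD37 were among the 10 largest ratios. The count was 90 higher and 38 lower of 11958 genes, or 64 and 13 of 11797 genes of at least 300 bp. At an adjusted p under 0.05, the authors' deposited table holds 75 genes higher and 8 lower at 6 hr, against 2 and 1 at 2 hr. Of those 83 genes at 6 hr only 42 passed the size rule, and CDH26 is not among the 83.

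At 24 hr CDH26 was at 0.210 RPKM in the control and 10.8 with IL-13, a 51.5-fold ratio. PAPSS2, which makes the sulfate donor of sulfotransferases, was 14.1-fold higher, GCNT3 17.2-fold, ALOX15, the 15-lipoxygenase, 8.28-fold, and SGK1 4.38-fold. DPP4, a cell-surface peptidase, was at 0.0378 RPKM in the control and 1.44 with IL-13, a log2 ratio of 3.49. IL31 was listed at 0 in the control and 1.18 RPKM with IL-13. UBE2F-SCLY, listed at 0 and at 3.96 RPKM, is a read-through transcript. Among the lower genes, C10orf99 was at 25.5 RPKM in the control and 3.62 with IL-13, DEFB1, a beta-defensin, at 56.4 and 13.4, CALML5 at 8.25 and 1.22, CALML3 at 7.36 and 1.59, THEM5 at 10.7 and 2.36, CLDN8 at 6.94 and 1.60, DLX2 at 7.26 and 1.80, and the cornified envelope precursor SPRR1B at 8.69 and 1.959. The skin-homing chemokine CCL27 was at 1.16 RPKM and listed at 0. Neither CCL27 nor IL31, both at low RPKM, passed an adjusted p under 0.05 in the authors' deposited table. The short genes SNORD38B, MIR1182 and SNORD100 had large ratios on few reads. There were 111 higher and 159 lower of 12524 genes, and 68 and 126 of 12389 genes of at least 300 bp. With a pseudocount of 1 the excess of lower genes was gone, at 77 higher and 78 lower. The authors' deposited table holds 53 higher and 87 lower at an adjusted p under 0.05 for this time, and 83 of these 140 passed the size rule.

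Gene lists fixed in advance gave the same outline. The random lists, here and below, draw genes independently of each other. A list whose genes vary together can thus reach an extreme percentile on a small difference between 2 single libraries. The percentiles at 2 and 6 hr are also not independent, since their controls appear to share a read set. They describe where a list lies and do not by themselves show an effect of IL-13. Among IL-13 responsive genes of epithelia, 8 of 18 expressed members were 2-fold higher at 2 hr, 12 of 20 at 6 hr and 12 of 21 at 24 hr, with 0 lower at each time. Their median log2 ratios were 0.84, 1.53 and 1.13, above all 10000 random lists at each time (percentile 100). The list was drawn up with knowledge of the study, so its count is not independent evidence. Squamous differentiation genes lay on the other side, with medians of -0.12, -0.42 and -0.67 (percentiles 0.08, 0 and 0) and 0 of 18, 2 of 18 and 7 of 19 members lower. At 24 hr these included KRT1 and KRT10, keratins of the suprabasal layers, at 109 and 27.8 RPKM and at 106 and 40.2 RPKM, and the cross-linking enzyme TGM1 at 53.0 and 25.5 RPKM. Basal squamous genes had medians of 0.04, -0.08 and -0.38 (percentiles 99.9, 0.02 and 0). Within that list KRT14 was at 287 and 137 RPKM and the nerve growth factor receptor NGFR at 6.34 and 2.46 RPKM at 24 hr, while SOX2 was higher at each time, from 10.1 to 26.7, from 16.4 to 37.7 and from 49.2 to 105 RPKM.

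Chemokines had medians of 0.19, 0.56 and -0.07 (percentiles 99.9, 100 and 15.4) over 8, 6 and 10 expressed members, and at 2 hr the median was 0.08, inside the central 95%, when an RPKM of 0.5 was enough. Only CCL26 was 2-fold higher at all 3 times, and CCL17 and CCL27 were lower at 24 hr, CCL17 at 2.40 and 0.696 RPKM. Growth factor immediate early genes had medians of -0.09, -0.10 and -0.31 (percentile 0 at each time) with no expressed member 2-fold changed. Relative to all genes, this list differed by -1.45 between the controls at 2 and 6 hr and by 0.93 between those at 6 and 24 hr. Inflammatory cytokines and NF-kB targets had medians of -0.08, -0.10 and -0.27 (percentiles 0.14, 0.55 and 0), and 3 of 17 were lower at 24 hr, IL36G at 1.06 and 0.181, IL11 at 2.48 and 1.02 and PTGS2 at 17.5 and 8.62 RPKM. Interferon-stimulated genes had medians of 0.13, 0.03 and 0.06 (percentiles 100, 98.1 and 92.2). Receptors and JAK-STAT genes had medians of 0.04, 0.06 and -0.02 (percentiles 88.5, 97.2 and 14.1). SOCS1 and CISH were higher at every time in that list, and IRS1, an adaptor of the IL-4 receptor, was lower at 24 hr at 2.82 and 1.14 RPKM. Cholesterol synthesis genes had medians of -0.02, -0.06 and -0.17 (percentiles 31.4, 0.86 and 0), cell cycle genes -0.02, -0.04 and -0.07 (percentiles 37.3, 1.53 and 0.35), and calpains and cell junctions 0.03, -0.08 and -0.10 (percentiles 99.7, 0.09 and 0.87), with CDH26 the 1 junction gene that was 2-fold higher at 6 and 24 hr. Columnar, fibroblast, unfolded protein response, histone modifying and housekeeping lists stayed inside the central 95% at all 3 times. Of the leukocyte and endothelial markers at most 2 were expressed, and VWF was higher at 24 hr, at 0.943 and 4.21 RPKM.

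**Figure D3:**
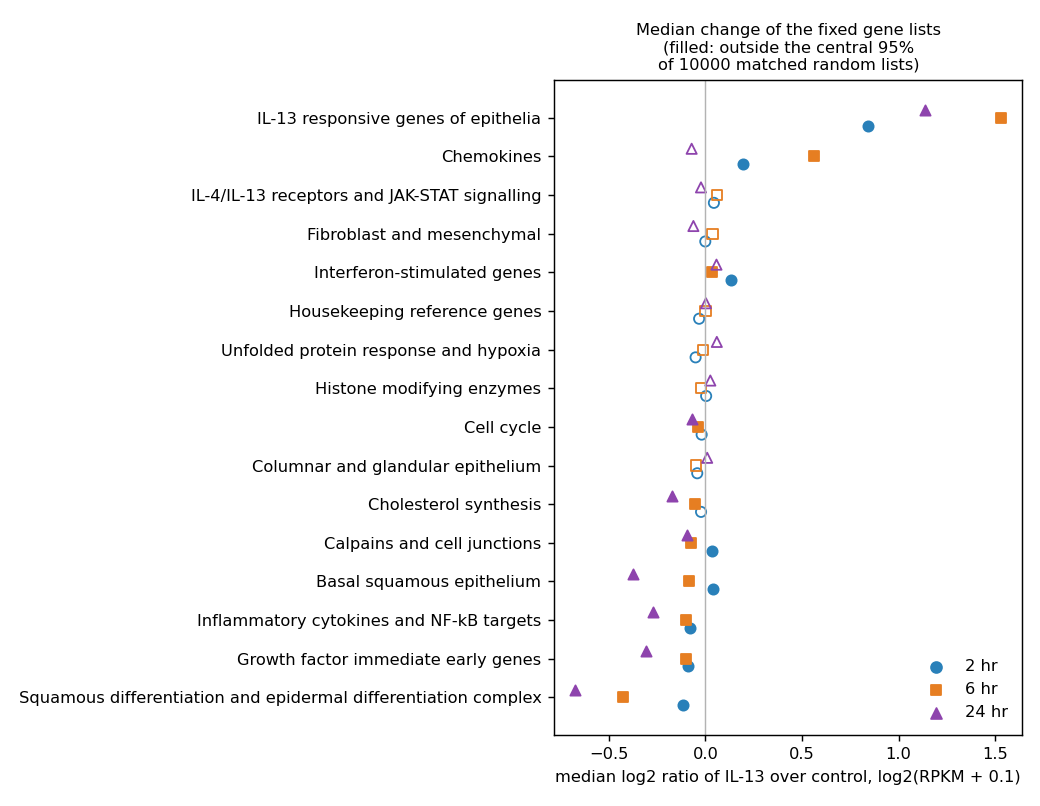
Each point is the median log2 ratio of IL-13 over control among the expressed members of a fixed gene list, on log2(RPKM + 0.1), at 2 hr (circles), 6 hr (squares) and 24 hr (triangles). Filled points lie outside the central 95% of 10000 matched random lists, and the IL-13 responsive genes lie farthest to the right, at 0.84, 1.53 and 1.13.

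Genes were also compared across the 3 times. Of those of at least 300 bp, 16 were 2-fold higher at each time, among them CCL26, SOCS1, CISH, GCNT3, HS3ST1, HAS2, HAS3, SERPINB3, SERPINB4, MMP7, LURAP1L, LIFR, SGK1, SOX2 and SYNPO. No gene of that length was 2-fold lower at all 3 times. In the limma fit over the 3 times, 0 of 11953 genes passed an adjusted p under 0.05, with 2025 at an unadjusted p under 0.05 and a smallest adjusted p of 0.114. With limma-trend 6 genes were called higher, with a pseudocount of 1 it was 7, and without the 2 hr pair 6 higher and 1 lower. Genes shorter than 300 bp, which rest on few reads, are among these calls, SNORD65 with the pseudocount of 1, and MIR1182 and the 1 lower gene, MIR1248, without the 2 hr pair. GCNT3 had the smallest p, with a log2 change of 3.72 ± 0.19 (SE), higher at 3 of 3 times. SOX2 (1.23 ± 0.07), HS3ST1 (2.32 ± 0.16), DENND4A (1.00 ± 0.06) and RUNX2 (0.99 ± 0.06) were close behind. So were genes lower at 3 of 3 times, among them CLCF1 (-0.68 ± 0.04) and ARHGAP29 (-0.64 ± 0.04). DENND4A, RUNX2, CLCF1, ARHGAP29, SNORD65 and MIR1248 were named after their values had been seen. Adjusted over the list alone, 13 of 18 IL-13 responsive genes rose and 3 fell, in a list drawn up with knowledge of the study. These calls treat the times as independent, although the controls at 2 and 6 hr appear to share a read set, so the spread behind them is understated. The mean r of 0.252 between the ratios of simulated unchanged genes was set by the equal noise assumed and does not measure by how much. CCL26 rose by 3.36 on the log2 scale, SERPINB4 by 3.08, SERPINB3 by 2.89 and HAS3 by 1.94, while IL4R, FOXQ1 and PIM1 fell by 0.24, 0.43 and 0.43. Adjusted over the list alone, 1 immediate early gene rose and 6 of 35 fell, among them JUN and DUSP5, and 3 of 39 interferon-stimulated genes rose, DDX58, IFIT2 and IFIH1. The squamous differentiation list had 0 of 18 by that limma test.

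The same size rule was applied between control libraries of different times. These pairs hold change over time, the controls at 2 and 6 hr appear to share a read set, and the control at 2 hr held brain transcripts, so they are no measure of the spread between independent libraries. From 2 to 6 hr 24 genes were higher and 283 lower of 12001. From 6 to 24 hr 2042 were higher and 767 lower of 12587, and from 2 to 24 hr 2072 and 714 of 12607. The median of all genes shifted by 0.10, 0.23 and 0.30 on the log2 scale in these pairs, and centring on it gave 20 and 332, 1436 and 1191, and 1165 and 1146. Between IL-13 libraries from 6 to 24 hr the split was 1869 and 628, or 1336 and 990 after centring. The IL-13 comparisons had medians of 0.00, 0.00 and 0.02.

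The ChIP-seq comparison asked where active marks differ after 6 hr of IL-13. H3K27Ac at the CCL26 start at 75401572 had M of -2.07 and -2.72 in the authors' deposited table, against 0.04 at the start at 75419064. SOCS1 had -1.98 and -2.14 and CISH -1.31 and -2.33 for H3K27Ac in the authors' deposited table. The other marks were under 2-fold there, with H3K4me3 at -0.54 for SOCS1 and -0.70 for CISH, and H3K9Ac at -0.87 and -0.77, in the authors' deposited table. H3K9Ac at the CCL26 starts was -2.89 at 75401572 and -0.33 at 75419064 in the authors' deposited table. A CAPN14 peak of H3K27Ac, at -3.08 in the authors' deposited table, was under the minimum level.

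Across the genome 9906 H3K4me3, 11968 H3K9Ac and 12440 H3K27Ac peaks reached the minimum level. Of these, 596 were 2-fold higher in library 1 and 477 in library 2 for H3K4me3, 454 and 430 for H3K9Ac, and 627 and 461 for H3K27Ac. The lowest M of H3K27Ac in the authors' deposited table belonged to OR10S1 (-5.56), ANPEP (-5.53) and the cytokine gene IL19 (-4.39), and the highest to APPL1 (4.05) and ERCC6L (4.01). For H3K9Ac, ANK1 (-4.21) and PPARG (-3.69) were among the peaks of low M in the authors' deposited table, and MIR4516 (4.17) and PKD1 (3.97) among those of high M. For H3K4me3 the authors' deposited table has RASIP1 (-3.22) and EN2 (-3.08) against ELF1 (4.44) and INSIG2 (4.06). The marks overlapped little. Shared and opposite starts are counted here as if library 1 had the same treatment in each mark, which the labels do not state. With the order reversed in a mark, shared and opposite would change places. Of starts higher in library 2, H3K9Ac and H3K27Ac shared 38 where independence gives 14.9, and in library 1 54 where it gives 26.1. H3K4me3 and H3K27Ac shared 30 against 15.3 in library 2 and 34 against 36.9 in library 1, and H3K4me3 and H3K9Ac 25 against 19.0 and 31 against 30.3. Opposite calls were no rarer than independence gives. Starts higher in library 2 for H3K9Ac and in library 1 for H3K27Ac numbered 47, where it gives 23.9, and the reverse 21 where it gives 16.3. For H3K4me3 in library 2 there were 39 against 21.1 with H3K9Ac and 33 against 25.2 with H3K27Ac, and for H3K4me3 in library 1 28 against 27.3 and 23 against 22.4.

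Promoters of genes with higher RNA at 6 hr had lower M, most of all for H3K27Ac. In the authors' deposited table M of H3K27Ac was -4.03 at GCNT3, -3.25 at SERPINB4, -2.97 at SERPINB3 and -2.32 at MMP7. The median M of 66 such promoters was -0.27 (percentile 0), against 0.09 for all genes, and 47 lay below 0. For H3K9Ac the median of 59 was -0.06 (percentile 0.55) and for H3K4me3 that of 50 was -0.03 (percentile 8.71). Among genes of at least 300 bp the medians were -0.47 over 45 genes (percentile 0), -0.36 over 39 (percentile 0) and -0.355 over 30 (percentile 0.02). The promoters of genes with lower RNA had medians of 0.37 for H3K4me3 (percentile 97.52), 0.20 for H3K9Ac (percentile 86.2) and 0.12 for H3K27Ac (percentile 62.2). These medians rest mostly on genes shorter than 300 bp, whose calls rest on few reads. They made up 18 of 21 for H3K4me3 and 18 of 25 for each of the others, and the 3 longer genes with an H3K4me3 value had a median of 0.41 (percentile 81.6). Across genes, which are not independent replicates, the Spearman correlation of M with the RNA log2 ratio was 0.0408, -0.0588 and -0.114 for H3K4me3, H3K9Ac and H3K27Ac, 3 relations in 1 family. Among IL-13 responsive genes, 6 of 17 promoters had M of H3K27Ac at or under -1, among them SOCS1, CISH, SERPINB3, SERPINB4 and TGM2, and the list median was -0.67 (percentile 0), with -0.14 for H3K9Ac (percentile 4.45) and -0.54 for H3K4me3 (percentile 0.115).

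**Figure D4:**
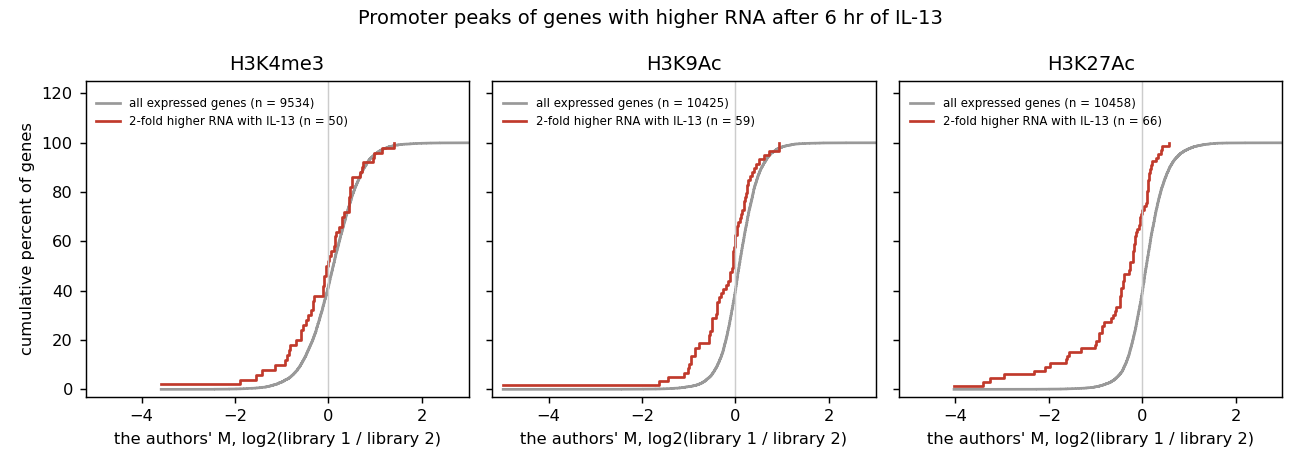
Cumulative percent of genes (vertical axis) by the authors' M, log2 of library 1 over library 2 (horizontal axis), for promoter peaks of all expressed genes (grey) and of genes 2-fold higher in RNA after 6 hr of IL-13 (red). For H3K27Ac 71.2% of the 66 red genes lie below 0 against 38.8% of all genes, and for H3K4me3 50% against 41.3%.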

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

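The tests on lower RNA after IL-13 and on the number of reads were chosen only after the results were seen. Each result here went opposite ways at 2 times, and no difference between times was tested, since each time has 1 library per group.

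NRGN, a brain protein, had a log2 ratio of -1.97 at 2 hr and 1.02 at 24 hr, a difference of 2.99. It belongs to the brain genes that stood high in the control at 2 hr. Of 54 other listed brain genes 40 were under 0.5 RPKM in the median of the remaining 5 libraries, and of these, whose values had not been looked at, 38, or 95% (Wilson interval 83.5% to 98.6%), were highest in that library, against 20% of 6174 other genes. The higher of the other controls reached a median of 0.0276 (0 to 0.182) of the control at 2 hr over 13 genes. Those 13 were picked after their values had been seen, and all 13 were highest in the control at 2 hr. Their low ratio was thus largely fixed by the choice, and it cannot decide on lower RNA after IL-13. The 40 genes not looked at had medians of 0.253 RPKM in the control at 2 hr and 0 in the other controls. They had, however, been kept for low values in the remaining libraries. RNA of another tissue in the read set used only for the control at 2 hr may account for them, and no biological explanation beyond treatment was tested.

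MIR1182 had a log2 ratio of -1.46 at 2 hr, 4.50 at 6 hr and 4.90 at 24 hr, differences of 5.96 and 6.36. MIR3685 and MIR4523 went from 3.74 and 3.96 at 2 hr to -3.69 and -3.55 at 24 hr, differences of -7.43 and -7.51. SNORD59A went from 3.94 at 2 hr to -4.37 at 24 hr, a difference of -8.31, and SNORD45B from 4.18 at 6 hr to -3.51 at 24 hr, a difference of -7.69. Few reads may account for this: over 178 calls of genes shorter than 300 bp the value in the higher library rested on a median of 4.0 reads (3.29 to 4.21), and 158 rested on 10 or fewer. A change of these genes after IL-13 stays open, since 54.4% (37 of 68, interval 42.7% to 65.7%) of those changed at 24 hr lay on the same side at 6 hr, against 79.3% of 193 longer genes.

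Basal squamous genes had a median of 0.04 at 2 hr, -0.08 at 6 hr and -0.38 at 24 hr, differences of -0.12 and -0.41. Calpains and cell junctions had 0.03, -0.08 and -0.10, differences of -0.11 and -0.13.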

How the results depend on the processing

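The RPKM minimums of 0.5 and 3, the limit of 300 bp, leaving out brain genes, the pseudocount of 1 in limma, and median-ratio scaling for lists and control pairs were chosen after the data had been seen. Of the results that answer a comparison 62 alternative values stayed within the limit set for them and 67 moved beyond it, 1 passed its threshold newly and 1 no longer did, and of the others 117 stayed and 3 did not. Without a minimum RPKM the balance at 2 hr turned to more lower than higher genes. Small list medians at 24 hr changed sign inside the central 95%, columnar genes from 0.01 to -0.01 and housekeeping genes from 0.00 to -0.02 with median-ratio scaling, and receptors and JAK-STAT genes from -0.02 to 0.01 at an RPKM of 0.5. The cause was not tested beyond what each setting itself removes or adds.

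Genes higher and lower by the size rule were 79 and 41 at 2 hr, 90 and 38 at 6 hr, and 111 and 159 at 24 hr. A pseudocount of 1 gave 40 and 20 at 2 hr, 49 and 15 at 6 hr, and 77 and 78 at 24 hr. Without a minimum RPKM there were 187 and 337, 257 and 187, and 382 and 457. An adjusted p under 0.05 in the authors' deposited table gave 2 and 1 at 2 hr, 75 and 8 at 6 hr, and 53 and 87 at 24 hr. An RPKM of at least 0.5 gave 107 and 94 at 2 hr, 134 and 67 at 6 hr, and 176 and 238 at 24 hr. An RPKM of at least 3 gave 37 and 7, 54 and 10, and 39 and 64. Genes of at least 300 bp gave 47 and 22 at 2 hr, 64 and 13 at 6 hr, and 68 and 126 at 24 hr. Without the listed brain genes 79 were higher and 27 lower at 2 hr.

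For the effect shared by the 3 times, limma called 0 genes, limma-trend 6 higher and a pseudocount of 1 gave 7 higher. Leaving out each pair gave 0 to 6 higher and 0 to 1 lower, with all calls made without the 2 hr pair, where the lower gene was shorter than 300 bp. Each fit with time as a term compares the libraries within a time, and without that term 0 genes were called, with 77 at an unadjusted p under 0.05.

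Peaks higher in library 1 and library 2 at 1.5-fold numbered 1829 and 1317 for H3K4me3, 1467 and 1068 for H3K9Ac, and 1737 and 1040 for H3K27Ac. At a p of 1e-05 in the authors' deposited table they were 156 and 100, 130 and 94, and 165 and 151. At a level of at least 100 they were 103 and 50, 86 and 33, and 130 and 57, and among common peaks 351 and 288, 201 and 151, and 271 and 155. The Spearman correlation with RNA was 0.0201 for H3K4me3 at 24 hr, and -0.0777 at 2 hr and -0.0460 at 24 hr for H3K27Ac. At 1.5-fold the shared starts in library 1 and 2 were 13.4% and 12.1% for H3K4me3 with H3K9Ac and 14.8% and 8.50% with H3K27Ac. For H3K9Ac with H3K27Ac they were 21.4% and 13.1%. At 2-fold these shares were 3.46% and 4.01%, 3.82% and 4.94%, and 9.69% and 7.45%. A looser limit also raises the share that independence gives. That share was not computed at 1.5-fold, so the rise is no measure of agreement between marks. In genes of at least 300 bp the promoter median of H3K4me3 was -0.355 for higher genes, now outside the central 95%, and 0.41 for the 3 lower genes, now inside it, in a smaller set of genes.

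Raw-read ratios, other windows around starts, overlap by the shorter peak, read minimums, prior counts, count models and total-read scaling were not run, because they need read counts, peak positions or a stated library order. Depth limits genes shorter than 300 bp, where calls rested on a median of 4.0 reads.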

Other observations

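The tests of the covariance and of genes higher at 24 hr were chosen only after the results were seen.

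Control libraries of different times differed in several gene groups, given here as medians relative to the median of all genes. Each time has 1 control library, and these libraries also differ in make-up, with 2 read sets at 2 and 6 hr, 1 of which appears to be shared, a single set at 24 hr, and brain transcripts at 2 hr, so time and library cannot be separated. Growth factor immediate early genes were lower in the control at 6 than at 2 hr, by 23 of 37 members and a median of -1.45 (percentile 0 of matched random lists), and higher at 24 than at 6 hr, by 21 of 36 and 0.93 (percentile 100). Chemokines lay at -1.44 and 1.27 in the same pairs (percentiles 0 and 99.8). Interferon-stimulated genes were at -0.55 from 2 to 6 hr (percentile 0) and 1.01 from 6 to 24 hr (percentile 100), with 24 of 39 higher. Squamous differentiation genes were at -0.51 (percentile 0) and 1.23 (percentile 100), with 11 of 20 higher at 24 hr, and cell cycle genes at 0.18 (percentile 100) and -0.87 (percentile 0), with 12 of 37 lower at 24 hr. With IL-13, immediate early genes lay at -1.56 from 2 to 6 hr (percentile 0), with 25 of 36 lower.

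Promoter marks of some fixed lists lay outside the central 95% of random lists, mostly for 1 mark only. Each list was looked at for each mark, and a few of so many would lie outside without any difference. M of H3K27Ac was higher in library 1 for NF-kB targets, with a median of 0.31 (percentile 98.4), CSF2, RELB and BIRC3 being 2-fold higher there, and for immediate early genes, at 0.24 (percentile 97.6), with PLAUR and ETV4. For H3K4me3 immediate early genes were at -0.08 (percentile 6.17, inside), with EGR1, EGR2 and DUSP1 2-fold higher in library 2 and EGR3 in library 1. Interferon-stimulated genes lay toward library 2, at -0.09 for H3K27Ac (percentile 0.38) and -0.10 for H3K9Ac (percentile 0.28), where 2 members were 2-fold higher in library 2 and 3 in library 1. Squamous differentiation genes had a median of 0.48 over 9 promoters for H3K9Ac (percentile 99.8) with KRT13 and DSG3. Fibroblast genes had -0.36 over 6 promoters for H3K9Ac (percentile 0.81), against 0.45 over 6 for H3K27Ac (percentile 96.9, inside). Columnar genes had -0.48 for H3K4me3 (percentile 0.26), against 0.205 for H3K9Ac and 0.34 for H3K27Ac (percentiles 83 and 97.46, both inside). Calpains and cell junctions had -0.25 for H3K4me3 (percentile 0.315), against 0.25 and 0.185 (percentiles 97.1 and 84.7, both inside).

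Among 11629 genes of at least 300 bp expressed at both times, log2 ratios at 2 and 6 hr correlated across genes (Pearson r 0.694, Spearman correlation 0.586), where the controls appear to share a read set. Unchanged genes were simulated with that shared set and with equal noise in every read set, sized from the observed ratios, any IL-13 response included. The mean r of 0.252 in these genes followed from this setup, whatever the data held. Their covariance was 0.0117 on average and 0.0204 at most, against 0.0316 observed. Noise sized in this way raises the simulated covariance and counts if genes responded. A shared set with more noise than the others was not simulated. The simulation therefore cannot decide whether the shared set is the whole cause. Of 39 and 57 of these genes higher at 2 and 6 hr, 31 were higher at both, where independent lists give 0.191 and the simulation 7.5 on average and 15 at most, while 1 was lower at both against 7.66 simulated. A response present at both times is a candidate explanation: of 68 genes of at least 300 bp higher at 24 hr, whose control is separate, 63.2% (51.4% to 73.7%) were above 0 at both, against 34.4% of all 12389 genes of that length. Part of the excess may still come from the shared control.

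The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The limma fit called 0 genes in the real split, so all 10 gave at least as many. With time as a term, a split that keeps both libraries of a time together compares only the time whose libraries it divides. The splits with the most calls were of this kind. They compared the IL-13 and control libraries at 24 hr alone, in opposite directions. These splits are thus not free of treatment, and the number of calls cannot decide on the effect shared by the 3 times.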
